A study of Mus musculus with 12 samples.

How the data were processed

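RNA was profiled on 12 expression arrays of C166 cells, a mouse endothelial cell line. Cells were transduced with a lentiviral vector that carries GFP alone, or with 1 of 2 vectors that carry GFP and an shRNA complementary to a stretch of the Vegfa promoter. The groups, 4 arrays each, are called GFP, VEGF-down and VEGF-up, as in the labels. The labels do not say whether the replicates are separate cultures, so the p-values measure only the spread between these samples. The replicate numbers recur in all groups, and the residual levels did not pair arrays of the same number, so no block was used.

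The authors deposited an array intensity per probe set and sample, on a linear scale, made with GCRMA per the submitters' processing notes, which give no version. That the scale is linear was read from the values, which run from 3.04 to 17470.06. The matrix holds 17370 probe sets, 1 for each Entrez gene, of which 64 are control probe sets. The authors also deposited 1 table of changed genes for each shRNA with a signed fold change and a T-statistic (both scores per the file headers). The p-value and q-value of each gene in the deposited tables come from a test that the file headers do not describe. The largest p among the listed genes is 0.00998 in the VEGF-down table and 0.00997 in the VEGF-up table. The smallest fold is 1.41 in the VEGF-down table and 1.22 in the VEGF-up table, so the lengths of the authors' tables cannot be compared.

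Intensities were taken to log2 with no offset and no further normalization. The 17306 probe sets that are not controls were tested. Of these, 16464 carry 1 gene symbol, 0 carry several and 842 carry none; the last were tested and counted but are not named. Symbols came from the platform table and a RefSeq gene table of assembly GRCm38.p6, matched on the Entrez number for all 16464 named probe sets. That table also gave the order of genes around Vegfa. The genome build behind the coordinates in the authors' deposited tables is not named there, so no coordinates are given.

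Differences between groups were estimated with limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 12 arrays with lmFit and moderated with eBayes and a variance trend on mean level. Tests were two-sided and p-values were adjusted by Benjamini-Hochberg over all 17306 probe sets of a comparison, with 0.05 as the threshold. The comparisons were VEGF-down against GFP, VEGF-up against GFP and VEGF-up against VEGF-down. "Rose", "fell" and "changed" are used for what passed this test. For Vegfa an exact two-sided permutation test of the 8 log2 values was added. Its smallest possible p with 4 arrays against 4 is 0.0286. Values are log2 differences with the standard error of the fit (SE), or group means with the standard deviation (SD), n = 4 arrays per group.

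Signal near background was judged from 66 chemosensory receptor probe sets, a class chosen after the data were seen. The 95th percentile of their mean levels, 3.09 on the log2 scale, served as the background level. Of the tested probe sets, 37.2% had a mean over the 12 arrays at or below it. For a gene at or below this level in the mean or on every array of 1 group, only the smallest fold against the background level is given, as "at least". The number of arrays limits the precision.

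The named genes follow a rule written before the data were examined. It takes Vegfa and, per comparison, the 12 genes with the largest rise and the 12 with the largest fall among changed genes whose arrays do not overlap between the groups and whose brighter group mean is above the median of all genes. It adds the 8 largest shared rises, the 8 largest shared falls and 6 genes of each kind changed in opposite directions by the shRNAs. From each of the authors' tables it takes the 3 largest rises and the 3 largest falls, and members of the fixed gene lists may be named. Unnamed models may be left out.

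There were 19 gene lists fixed before the data were examined. They cover VEGF ligands and receptors, genes beside Vegfa, VEGF-responsive and tip cell genes, endothelial markers, Notch and arteriovenous genes, interferon-stimulated genes, NF-kB and inflammatory genes, RNA interference machinery, chromatin silencing enzymes, hypoxia and glycolysis, cell cycle, p53 targets, unfolded protein and ATF4 response, cholesterol synthesis, NRF2 and oxidative stress, extracellular matrix, ribosomal proteins, smooth muscle and fibroblast markers, and blood cell and macrophage markers. Each was tested against all other genes with camera (limma) at a preset correlation of 0.01, and p-values were adjusted over the 19 lists of a comparison. Members past the test were counted with p-values adjusted over all genes and again adjusted over the list alone. Camera with an estimated correlation and fry were the alternatives. Another 6 lists were written after the first results were seen and are used only in the additional observations.

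The comparisons against GFP share the 4 GFP arrays. The count of genes changed by both shRNAs was therefore set beside the count for independent lists, the mean over 20 simulated data sets with unchanged groups and the counts with the GFP arrays divided between the comparisons in all 6 ordered ways, 2 arrays each.

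The fit and the list test were tested on simulated data before use, with 17306 genes drawn from the real means and spreads, 100 genes changed by 0.5 and 100 by 1 on the log2 scale. For VEGF-down against GFP, 95% of the genes changed by 0.5 were recovered, with 19 unchanged genes called. For VEGF-up against GFP the share was 92%, with 4 unchanged genes called. For VEGF-up against VEGF-down it was 96%, with 8 called. All 100 genes changed by 1 were recovered in each comparison. In separate simulated data only the unfolded protein and ATF4 response list was shifted, and it passed the list test in each comparison. Of the other lists, 1 was called between the shRNA groups (camera adjusted p = 0.0472) and none against GFP. Genes were drawn independently of each other, so these data cannot test how the list test handles correlated genes.

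The alternatives were other thresholds, filters on dim probe sets, no variance trend, quantile normalization, median centring of each array, a replicate block, only the compared groups in the fit and leaving out each array. Scaling each array to its 12 poly-A spike-in probe sets and keeping only the 10972 probe sets above background in at least 1 group were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6. The shRNA sequences are not in the sources used here, so no search for matching transcripts was made.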

Results

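Gene expression was measured on 12 arrays of C166 cells, a mouse endothelial line, collected 7 days after transduction with lentiviral vectors. The GFP group carried the marker gene alone. The VEGF-down and VEGF-up groups carried GFP and an shRNA complementary to a part of the Vegfa promoter, named after the change in Vegfa that each shRNA was chosen to bring about. Each group had 4 arrays. The median intensity of the arrays lay between 35.8 and 37.5, and between 62.5% and 63.3% of the tested probe sets were above the background level on each array. The mean correlation across genes of an array with the others of its group was at least 0.9987, while no VEGF-down array exceeded 0.9938 with an array of another group. The first principal component held 71.7% of the variance. The title of the series puts the question: which genes other than Vegfa differ in cells that carry these shRNAs.

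Vegfa, the growth factor gene on chromosome 17 whose promoter the shRNAs were aimed at, moved as the group names say. Its log2 level was 7.20 ± 0.11 (SD, n = 4) in GFP cells, 6.54 ± 0.06 in VEGF-down cells and 7.54 ± 0.16 in VEGF-up cells. Against GFP cells it was 1.58 times lower in VEGF-down cells, a log2 difference of -0.66 ± 0.08 (SE, adjusted p = 5.76e-05), and all 4 arrays lay below all 4 GFP arrays (exact permutation p = 0.0286, the smallest possible). In VEGF-up cells it was 1.27 times higher, a log2 difference of 0.34 ± 0.08 (adjusted p = 0.0134). There the arrays overlapped, with an exact permutation p of 0.0571. With the arrays scaled to poly-A spike-ins, RNAs added before labelling, this rise was 0.17 with an adjusted p of 0.1002. Between the shRNA groups Vegfa differed 2.01-fold, a log2 difference of 1.004 ± 0.08 (adjusted p = 1.74e-06, exact permutation p = 0.0286).

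**Figure D1:**
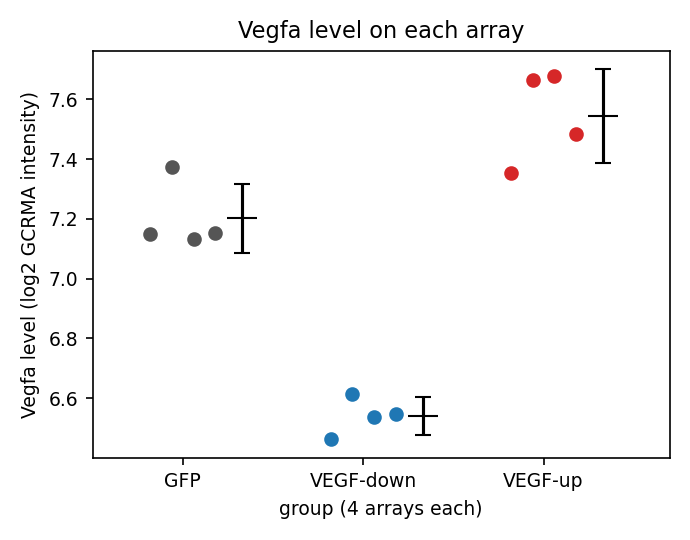
Level of Vegfa on each array, as the log2 of the deposited GCRMA intensity, by group; points are arrays and the bars show the mean and SD of 4 arrays. The VEGF-down arrays lie between 6.46 and 6.61 and the GFP arrays between 7.13 and 7.37, and the VEGF-up arrays, between 7.35 and 7.68, overlap the highest GFP array.

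VEGF-down cells differed from GFP cells in many genes besides Vegfa. The receptor gene Kdr, which encodes the main signalling receptor for VEGF-A, rose 10.1-fold, from a log2 level of 4.96 to 8.30 (log2 change 3.33 ± 0.09, adjusted p = 6.33e-10). The imprinted noncoding RNA H19 was 25.3 times lower (-4.66 ± 0.10, adjusted p = 1.42e-10). Car6, Tnnt2, Tnni1 and Aldh1l2 were among the largest falls, and interferon-stimulated genes rose as a group relative to other genes, with a median that turned negative with spike-in scaling (0.21 to -0.10). Of 17306 probe sets, 2521 rose and 2837 fell, 5358 in all or 31.0%. Most changes were small, with a median size of 0.29 on the log2 scale, and 167 rises and 154 falls reached 2-fold.

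Vat1l rose at least 33.9-fold from a GFP mean below the background level (adjusted p = 2.86e-14). Tnfsf9, a TNF family ligand that costimulates T cells, rose 19.7-fold, and Dkk2, a secreted modulator of Wnt signalling, rose 13.7-fold. The keratin genes Krt8 and Krt76 rose at least 5.91-fold and at least 7.62-fold from levels below background in all GFP arrays, and the organic anion transporter gene Slco1a5 rose at least 6.15-fold in the same way. Olr1, a receptor for oxidised LDL, rose 8.55-fold and the cytochrome P450 gene Cyp2f2 8.14-fold. Slc2a3, which encodes the glucose transporter GLUT3, rose 7.41-fold, Hoatz 6.95-fold and Hhip, which encodes a protein that binds hedgehog ligands, 6.91-fold. Among the falls, Car6, a secreted carbonic anhydrase gene, was 19.7 times lower. Tnnt2 and Tnni1, which encode troponins of heart and slow skeletal muscle, were 18.3 and 10.3 times lower. Aldh1l2, a mitochondrial folate enzyme gene, was 9.98 times lower, and Cth, whose enzyme makes cysteine, 8.47 times lower. The matrix genes Postn, Lum and Aspn were 8.77, 7.96 and 6.67 times lower. Sema3d, which encodes a secreted guidance protein, was 7.21 times lower, Saa3, an acute-phase gene, 7.14 times lower, and Agtr1a, an angiotensin II receptor gene, 6.71 times lower.

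**Figure D2:**
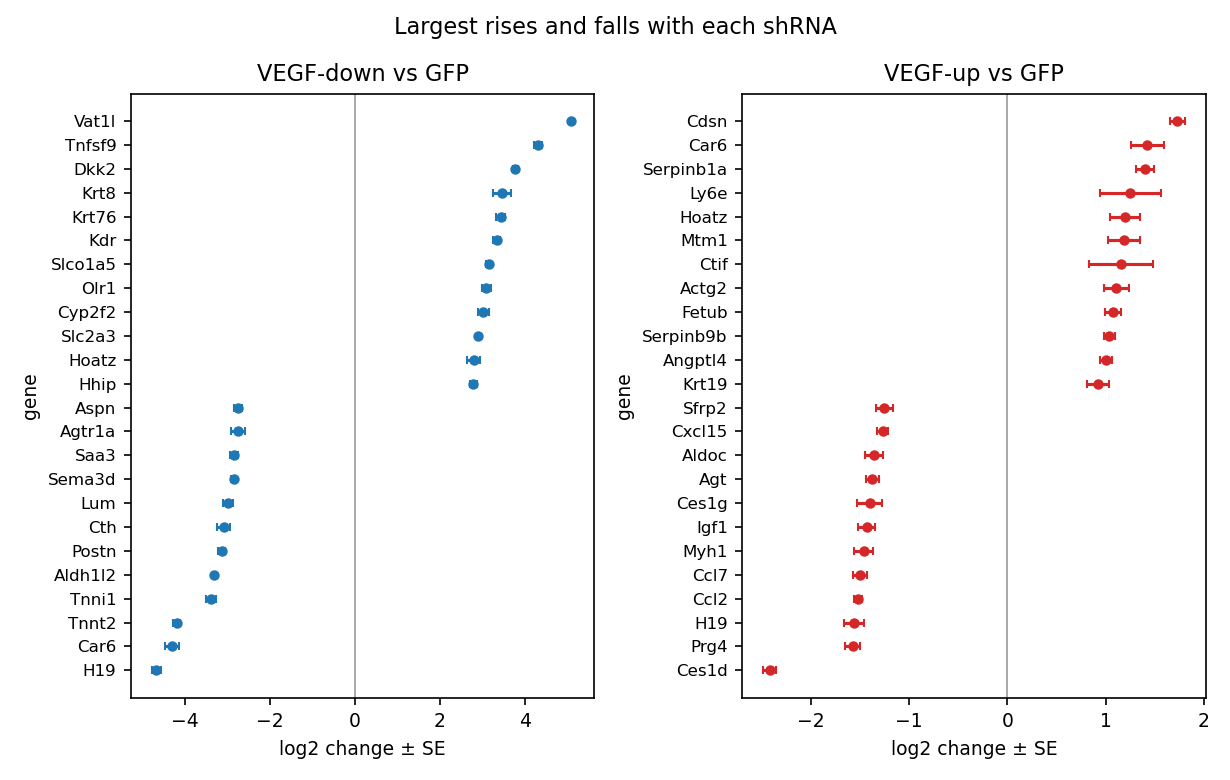
Log2 change against GFP cells, with its SE, of the 12 genes with the largest rise and the 12 with the largest fall by the fixed rule, for VEGF-down (left) and VEGF-up (right), 4 arrays per group. The axes differ, since falls reach -4.66 (H19) on the left and -2.42 (Ces1d) on the right; Vat1l, Krt8, Krt76 and Slco1a5 had means below background in GFP cells, so their plotted size has no fixed meaning.

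The list of genes for the unfolded protein and ATF4 response was lower in VEGF-down cells. Of its 31 measured genes, 2 rose and 18 fell (2 and 19 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 6.67e-07). The falls included the transcription factor gene Atf4 (-0.62), the pseudokinase gene Trib3 (-2.24), the amino acid transporter gene Slc7a5 (-1.51), the mitochondrial folate gene Mthfd2 (-1.30) and asparagine synthetase, Asns (-1.22). The chaperone gene Hspa5 fell less (-0.26), and the chaperone gene Dnajb9 rose (0.36). Of 44 interferon-stimulated genes, 19 rose and 1 fell (20 and 1 over the list alone), with a median of 0.21 (adjusted p = 1.72e-06); with spike-in scaling the median was -0.10, though the list was still higher than other genes. Gbp2, a GTPase gene, rose 3.16-fold, Ifit1 2.25-fold, Ifi35 1.80-fold and Ddx58, which encodes the RNA sensor RIG-I, 1.71-fold. The only member that fell, Cxcl10, was below background in both groups. Of 18 smooth muscle and fibroblast markers, 1 rose and 10 fell (1 and 12 over the list alone), with a median of -0.36 (adjusted p = 0.000645). The falls included Lum, the myosin light chain kinase gene Mylk (-1.87), the transcription factor gene Tcf21 (-0.79) and Tagln (-0.66), and the rise was in S100a4 (0.33). These 3 lists also passed the test with an estimated correlation, each at an adjusted p of 0.0145. Of 37 cell cycle genes, 3 rose and 21 fell (3 and 25 over the list alone), with a median of -0.27 (adjusted p = 0.000726). Its call was lost with an adjusted p = 0.316 with an estimated correlation. The mitotic genes Aurka (-0.60), Ccnb2 (-0.55), Prc1 (-0.55) and Mad2l1 (-0.53) fell, while Ccnd1, which encodes cyclin D1, rose (0.49).

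The other 15 lists did not pass the test in VEGF-down cells, though single members changed. The hypoxia and extracellular matrix lists passed it with 6 of 8 alternatives each, among them quantile normalization (0.00373 and 0.000915), but not with an estimated correlation (0.122 and 0.499) or median centring (0.1797 each). The NF-kB list passed it with 4 and the p53 list with 3. Of 25 hypoxia and glycolysis genes, 4 rose and 14 fell (4 and 16 over the list alone, adjusted p = 0.0527), with Egln3, a HIF prolyl hydroxylase gene, at -1.57 and the ER oxidase gene Ero1a at -1.43. Of 34 extracellular matrix genes, 6 rose and 17 fell (6 and 19 over the list alone, adjusted p = 0.0512). Loxl2 (-1.73) and the basement membrane collagen genes Col4a1 (-1.10) and Col4a2 (-1.01) fell, while the protease gene Mmp3 (1.32) and its inhibitor gene Timp1 (1.33) rose. Of 24 NF-kB and inflammatory genes, 5 rose and 12 fell (5 and 13, adjusted p = 0.0908), with Ccl20 at -1.28 and Il6 at 1.88. Of 24 p53 targets, 9 rose and 5 fell (9 and 6, adjusted p = 0.0650; median 0.03, and -0.28 with spike-in scaling), with Perp at 2.17, Zmat3 at 1.02 and Pmaip1 at -1.51. Of 16 cholesterol synthesis genes, 2 rose and 9 fell (2 and 10, adjusted p = 0.0908), with Mvd at -0.91. Of 20 NRF2 and oxidative stress genes, 4 rose and 6 fell (4 and 9, adjusted p = 0.273), with the heme oxygenase gene Hmox1 at -1.13. Of 18 chromatin silencing enzymes, 3 rose and 7 fell (4 and 9, adjusted p = 0.356), with the Polycomb gene Suz12 at -0.45 and Setdb1 at 0.46. Of 12 ribosomal protein genes, 2 rose and 5 fell (3 and 7, adjusted p = 0.399).

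Among 10 VEGF ligand and receptor genes, 2 rose and 2 fell in VEGF-down cells (3 and 2 over the list alone, adjusted p = 0.597); the median was -0.02 and the mean 0.26. Kdr rose, as did the coreceptor gene Nrp1 (1.76-fold). Vegfa fell and so did Vegfc, the ligand of lymphatic vessels (1.78 times lower). Of 19 VEGF-responsive and tip cell genes, 2 rose and 5 fell (2 and 5, adjusted p = 0.183). Rnd1 (-1.26) and the immediate-early genes Egr2 (-0.96), Nr4a1 (-0.82) and Egr1 (-0.70) fell, and Igfbp3 rose (0.89). Of 17 Notch and arteriovenous genes, 4 rose and 1 fell (3 and 0, adjusted p = 0.399), with the vein transcription factor gene Nr2f2 at 0.48 and the ligand gene Jag1 at 0.43; the median, -0.01, had the other sign than the test. Of 19 genes of the RNA interference machinery, 2 rose and 2 fell (2 and 1, adjusted p = 0.365), with Tnrc6b at 0.62, Ago4 at 0.41 and Ago1 at -0.47; here too the median, -0.00, and the test differed in sign. Of 15 genes beside Vegfa, 1 rose and 4 fell (1 and 5, adjusted p = 0.531). Gtpbp2, 4 protein-coding genes away, fell (-0.40), as did Mad2l1bp (-0.28), 3 genes away, while the gene next to Vegfa on that side, Mrps18a, was at -0.08. Of 26 endothelial markers, 1 rose and 1 fell (1 and 1, adjusted p = 0.531). Of 16 blood cell and macrophage markers, 1 rose and 0 fell (1 and 0, adjusted p = 0.675).

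Directions in this comparison are relative to the median of all genes, which was -0.01 as deposited and -0.32 with spike-in scaling. Rises made up 47.1% of the changes as deposited, 23.8% after median centring and 4.48% with spike-in scaling. After median centring 5050 of the 10708 changes were at background, against 424 of 5358 as deposited. The share of rises was 50.8% with only probe sets above background and 50.6% after quantile normalization. With that scaling the rises of Dnajb9, S100a4, Setdb1, Nr2f2, Jag1 and Ago4 did not pass the test.

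VEGF-up cells differed less from GFP cells. Of 17306 probe sets, 1165 rose and 1126 fell, 2291 in all or 13.2%, and 12 rises and 26 falls reached 2-fold. The carboxylesterase gene Ces1d was 5.36 times lower, falling from a log2 level of 8.80 to 6.37 (-2.42 ± 0.06, adjusted p = 2.22e-08). Cdsn, which encodes a protein of epidermal cell junctions, rose 3.33-fold (1.73 ± 0.07, adjusted p = 2.70e-07). Inflammatory genes fell as a group, and the unfolded protein and ATF4 response list rose relative to other genes, with a median that turned negative with spike-in scaling (0.14 to -0.03).

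The other large rises in VEGF-up cells were those of Car6 (2.68-fold), the serine protease inhibitor genes Serpinb1a (2.64-fold) and Serpinb9b (2.06-fold), Ly6e (2.39-fold) and Hoatz (2.29-fold). Mtm1, which encodes a phosphoinositide phosphatase, rose 2.28-fold, and Ctif, whose product acts in translation initiation, 2.23-fold (adjusted p = 0.0413). The smooth muscle actin gene Actg2 rose 2.16-fold, Fetub 2.11-fold, Angptl4, which encodes an inhibitor of lipoprotein lipase, 2.01-fold and the keratin gene Krt19 1.89-fold. Among the falls, Prg4, which encodes the lubricant proteoglycan lubricin, was 2.98 times lower and H19 2.96 times lower. The chemokine genes Ccl2, Ccl7 and Cxcl15 were 2.88, 2.84 and 2.41 times lower. The fast skeletal myosin gene Myh1 was 2.76 times lower, the growth factor gene Igf1 2.71 times lower and Ces1g 2.65 times lower. Agt, the angiotensinogen gene, was 2.60 times lower, the glycolytic gene Aldoc 2.57 times lower and Sfrp2, which encodes a secreted Wnt inhibitor, 2.39 times lower.

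The unfolded protein and ATF4 response list was higher in VEGF-up cells. Of 31 genes, 15 rose and 0 fell (20 and 0 over the list alone), with a median of 0.14 (adjusted p = 6.80e-14; 0.00237 with an estimated correlation); with spike-in scaling the median was -0.03, though the list was still higher than other genes. Trib3 (0.59), Slc7a5 (0.55), Ppp1r15a, a phosphatase subunit gene of the stress response (0.54), Atf5 (0.40) and Asns (0.32) rose, and Atf4 itself was at 0.07 (adjusted p = 0.0913), and at -0.10 with spike-in scaling. Of 24 NF-kB and inflammatory genes, 2 rose and 14 fell (2 and 14 over the list alone), with a median of -0.41 (adjusted p = 7.74e-07; 0.0462 with an estimated correlation), and of -0.26 without GFP replicate 2, which stood apart in the mean level of this list (7.50). Besides Ccl2 and Ccl7, the adhesion genes Selp (-1.21), Icam1 (-0.60) and Vcam1 (-0.56) fell, as did the chemokine gene Cxcl1 (-0.94), the acute-phase gene Saa3 (-0.85), Birc3 (-0.67) and the NF-kB inhibitor gene Nfkbia (-0.52); Il6 rose (0.71).

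Another 5 lists passed the test in VEGF-up cells but not with an estimated correlation. Of 24 p53 targets, 9 rose and 2 fell (9 and 3 over the list alone), with a median of 0.10 as deposited and -0.07 with spike-in scaling (adjusted p = 1.69e-05; adjusted p = 0.0662 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a (0.78), Zmat3 (0.51), Perp (0.46), Trp53inp1 (0.43) and Ccng1 (0.39) rose. Of 16 cholesterol synthesis genes, 0 rose and 8 fell (1 and 11), with a median of -0.22 (adjusted p = 3.79e-05; adjusted p = 0.124 with an estimated correlation), among them Hsd17b7 (-0.43), Stard4 (-0.40) and Lss (-0.30). Of 44 interferon-stimulated genes, 0 rose and 9 fell (0 and 10), with a median of -0.08 (adjusted p = 0.00399; adjusted p = 0.124 with an estimated correlation), led by Ifi27l2a (-1.01), Ifit1 (-0.89) and Samd9l (-0.48). Of 37 cell cycle genes, 1 rose and 9 fell (2 and 18), with a median of -0.13 (adjusted p = 0.0259; adjusted p = 0.436 with an estimated correlation), among them Birc5 (-0.41) and Cenpe (-0.39). Of 16 blood cell and macrophage markers, 0 rose and 2 fell (0 and 2), Cd14 (-1.04) and Csf1r (-0.25), with a median of -0.02 (adjusted p = 0.0436; adjusted p = 0.436 with an estimated correlation). This last call was also lost after quantile normalization (0.153) and median centring (0.0942), and the last 2 calls each without 3 of the 8 arrays, left out in turn.

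The other 12 lists did not pass the test in VEGF-up cells. The hypoxia and extracellular matrix lists passed it with 6 of 8 alternatives each, though not with an estimated correlation (0.183 and 0.684) or a replicate block, and the smooth muscle list with 5. Of 10 VEGF ligand and receptor genes, 2 rose and 4 fell (2 and 4 over the list alone, adjusted p = 0.520): Kdr (0.51) and Vegfa rose, and Vegfc (-0.84), Nrp2 (-0.66), Nrp1 (-0.21) and Vegfd (-0.16) fell. Of 15 genes beside Vegfa, 1 rose and 1 fell (1 and 1, adjusted p = 0.845), Gtpbp2 at 0.40 and the NF-kB inhibitor gene Nfkbie, 9 genes away on the other side, at -0.57; the median was -0.00 and the test leaned the other way. Of 34 extracellular matrix genes, 5 rose and 13 fell (6 and 18, adjusted p = 0.0816), with Mmp3 at -1.24, Postn at -0.77 and Col18a1 at 0.57. Of 25 hypoxia and glycolysis genes, 1 rose and 6 fell (2 and 10, adjusted p = 0.107), with the pyruvate dehydrogenase kinase gene Pdk1 at -0.79. Of 18 smooth muscle and fibroblast markers, 3 rose and 6 fell (3 and 8, adjusted p = 0.139), with Actg2 at 1.11, Cnn1 at 0.83 and the receptor gene Pdgfra at -0.67. Of 19 VEGF-responsive and tip cell genes, 0 rose and 3 fell (0 and 3, adjusted p = 0.428), Nr4a1 (-0.70), Igfbp3 (-0.35) and Egr1 (-0.23). Of 20 NRF2 and oxidative stress genes, 4 rose and 5 fell (5 and 6, adjusted p = 0.934), with Hmox1 at -0.83; the median was -0.05 and the test leaned the other way. The counts of rises and falls were 3 and 0 for Notch and arteriovenous genes (3 and 0 over the list alone, adjusted p = 0.465), 2 and 0 for endothelial markers (1 and 0, 0.919), 1 and 1 for the RNA interference machinery (1 and 1, 0.934), 0 and 1 for chromatin silencing enzymes (0 and 1, 0.934) and 0 and 1 for ribosomal protein genes (0 and 1, 0.465). In these 5 lists the median, between -0.01 and -0.00, was negative; the test pointed down for the endothelial markers and up for the other 4, and the mean was 0.01 for the endothelial markers.

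**Figure D3:**
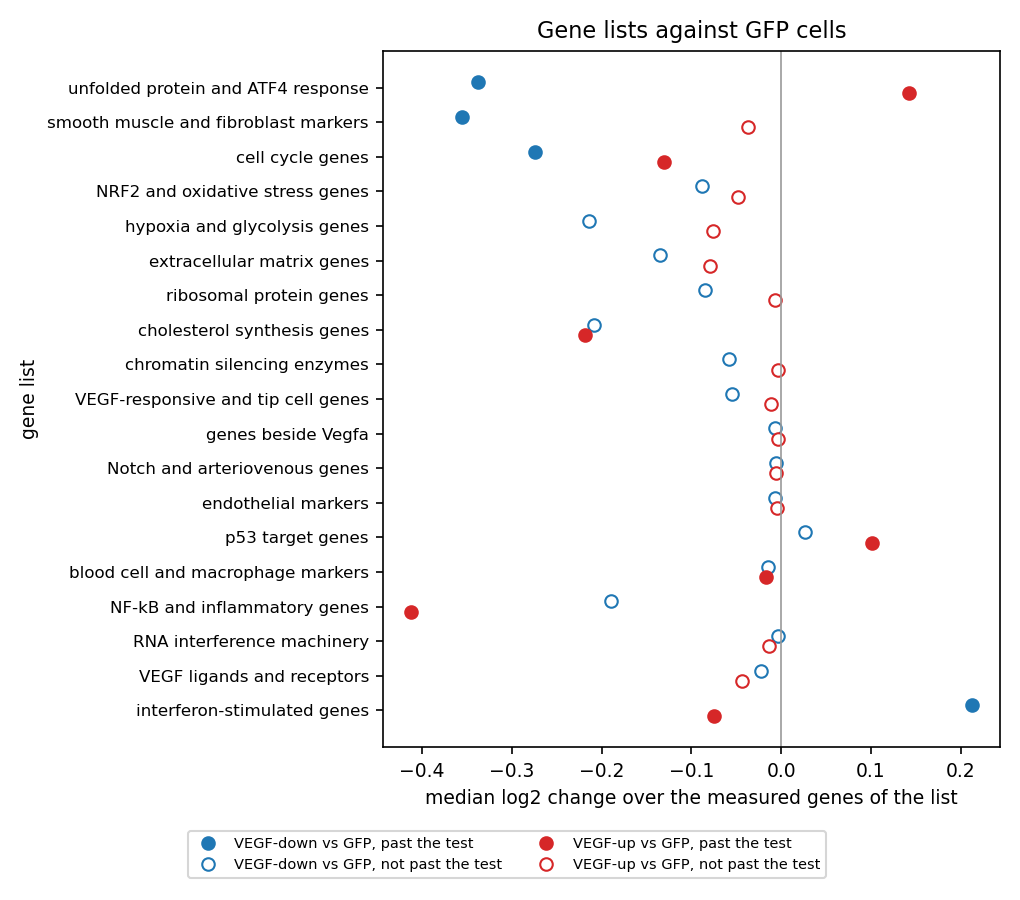
Median log2 change against GFP cells over the measured genes of each of the 19 fixed lists, for VEGF-down (blue) and VEGF-up (red) cells, 4 arrays per group; filled points passed the camera test with a preset correlation. The unfolded protein and ATF4 response list stands at -0.34 and 0.14 and the interferon-stimulated genes at 0.21 and -0.08; with spike-in scaling the 0.14 becomes -0.03 and the 0.21 becomes -0.10.

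As deposited the median of all genes in VEGF-up cells was -0.01, and with spike-in scaling -0.18. The poly-A spike-ins behind this scaling were 0.171 higher than in GFP cells, but the arrays overlapped (exact permutation p = 0.0857). Adjusted over all control classes and comparisons, that p was 0.138, so a difference in spike-ins was not established here. Rises made up 50.9% of the changes as deposited and 5.32% with spike-in scaling. With that scaling the rises of Asns, Ccng1 and Gtpbp2 did not pass the test, and with only the compared groups in the fit Ctif, Ly6e, Il6, Vegfd and Egr1 did not. With 1 of the 8 arrays left out in turn, the calls of Ctif and Vegfd were lost 6 times and that of Il6 5 times.

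The shRNA groups also differed directly, which asks what depends on the shRNA and not on carrying one. The unfolded protein and ATF4 response list was higher in VEGF-up than in VEGF-down cells, and interferon-stimulated genes were lower. Car6 was 52.9 times higher in VEGF-up cells (5.72 ± 0.17, adjusted p = 8.53e-10), and Vat1l, with a VEGF-up mean below background, was at least 34.0-fold lower (adjusted p = 2.78e-14). Of 17306 probe sets, 2608 were higher and 2680 lower in VEGF-up cells, 5288 in all or 30.6%, of which 179 and 222 reached 2-fold. The median of all genes was 0.14 with spike-in scaling. The higher share of 49.3% became 73.2% with that scaling and 78.3% after median centring, where 5103 of 11521 changes were at background. It was 49.7% with only probe sets above background and 52.8% after quantile normalization.

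Further genes with much higher levels in VEGF-up than VEGF-down cells were Cth (log2 difference 3.98), Aldh1l2 (3.75), Tnni1 (3.73), Angptl6 (3.47), Tnnt2 (3.31), Cdsn (3.26), H19 (3.10), Trib3 (2.84), the serine synthesis gene Psph (2.54) and Lum (2.53). Ly6e, below background in all VEGF-down arrays, was at least 5.38-fold higher. Lower in VEGF-up cells were Dkk2 (-3.96), Cyp2f2 (-3.72), Tnfsf9 (-3.58), Olr1 (-3.35), Prg4 (-3.19), Fxyd3, which encodes an ion pump regulator (-3.10), Slc2a3 (-3.05), Ces1g (-3.02) and Kdr (-2.83). Krt76, Slco1a5 and Krt8, below background in all VEGF-up arrays, were at least 7.62-fold, 6.15-fold and 5.91-fold lower.

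Of the 31 unfolded protein and ATF4 response genes, 23 were higher and 1 lower in VEGF-up than in VEGF-down cells (25 and 1 over the list alone), with a median of 0.59 (adjusted p = 3.71e-14; 0.00221 with an estimated correlation). Of 44 interferon-stimulated genes, 0 were higher and 23 lower (0 and 24), with a median of -0.36 (adjusted p = 1.61e-08; 0.00845 with an estimated correlation). Of 37 cell cycle genes, 14 were higher and 5 lower (14 and 5), with Tpx2 at 0.55 and Rrm1 at -0.44 (median 0.12, adjusted p = 0.0466; adjusted p = 0.502 with an estimated correlation). Of 18 smooth muscle and fibroblast markers, 8 were higher and 3 lower (8 and 3), with Lum at 2.53, Actg2 at 1.67 and S100a4 at -0.93 (median 0.15, adjusted p = 0.0466; adjusted p = 0.133 with an estimated correlation). These last calls were also lost after quantile normalization (0.110 for each) and after median centring (0.690 and 0.3002), and without 4 and 5 of the 8 arrays, left out in turn. Without VEGF-up replicate 3 the median of the smooth muscle list was 0.04. The other 15 lists did not pass the test. Among them, 18 extracellular matrix genes were higher and 8 lower (18 and 8 over the list alone, adjusted p = 0.0635), and 11 hypoxia and glycolysis genes were higher and 5 lower (12 and 5, adjusted p = 0.165). In the NRF2 list 11 genes were higher and 4 lower (11 and 5, adjusted p = 0.178), and in the NF-kB list 3 were higher and 8 lower (6 and 8, adjusted p = 0.207; median -0.03, and 0.10 with spike-in scaling).

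Of the VEGF ligand and receptor genes, Vegfa was higher in VEGF-up than in VEGF-down cells and 4 were lower (1 and 4 over the list alone, adjusted p = 0.165; median -0.06, and 0.08 with spike-in scaling), among them Kdr, Nrp1 (-1.02) and Nrp2 (-0.55). This list passed the test with 3 of 8 alternatives, among them median centring (0.0434) and spike-in scaling (0.0431), but not with an estimated correlation (0.443). Of the genes beside Vegfa, 4 were higher and 2 lower (4 and 2, adjusted p = 0.589), with Gtpbp2 at 0.80 and Nfkbie at -0.63. Of the VEGF-responsive and tip cell genes, 6 were higher and 2 lower (7 and 2, adjusted p = 0.237), with Rnd1 at 1.43 and Igfbp3 at -1.24. In the p53 list 7 were higher and 6 lower (8 and 7, adjusted p = 0.954), with Pmaip1 at 1.52 and Perp at -1.71. In the RNA interference list 4 were higher and 4 lower (5 and 7, adjusted p = 0.609; median -0.05, and 0.08 with spike-in scaling), with Ago1 at 0.32 and Tnrc6b at -0.68. Of the chromatin silencing enzymes 5 were higher and 2 lower (5 and 2, adjusted p = 0.295), with Suz12 at 0.52 and Setdb1 at -0.39. The counts of higher and lower genes were 5 and 1 for ribosomal protein genes (5 and 1, 0.165), 4 and 4 for cholesterol synthesis genes (4 and 4, 0.954) and 2 and 1 for endothelial markers (2 and 1, 0.680). They were 0 and 4 for blood cell and macrophage markers (0 and 4, 0.237) and 2 and 4 for Notch and arteriovenous genes (2 and 4, 0.693); the medians of these lists were 0.00, while the test pointed down.

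Both shRNAs changed 1586 of the same probe sets, of which 396 rose with both, 460 fell with both, 383 fell in VEGF-down and rose in VEGF-up cells, and 347 did the reverse. Independent lists of the same lengths would share 170, 185, 191 and 164. Above background the shared counts were 396, 441, 382 and 347, against 266, 244, 257 and 253 for independent lists. With the GFP arrays divided so that the comparisons share none, the medians were 263, 313.5, 288 and 258.5. Simulated groups without change that share the GFP arrays gave 0.05 genes or fewer of each kind. Without change almost no gene passes the test in either comparison. These counts therefore cannot show how far shared arrays raise the overlap of genes that do change. Changes in the same direction made up 54.0% of the shared genes. Across all genes, which are not independent replicates, the correlation of the changes was 0.0894, and groups without change that share controls gave 0.502. A correlation also depends on the spread of the changes, so these values cannot be compared directly. The covariance was 0.00442, against 0.00156 in the simulated groups, and 67.8% of the genes had the same sign, against 66.6%. With the GFP arrays divided as above, the median covariance was 0.00213, the median correlation 0.0407 and the median share of equal signs 64.0%.

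Genes that rose with both shRNAs were led by Serpinb1a (1.20 in VEGF-down and 1.40 in VEGF-up cells), Hoatz (2.80 and 1.20), Ctif (1.48 and 1.16, the latter lost without 6 of 8 arrays), Serpinb9b (1.60 and 1.04) and Krt19 (1.97 and 0.92), followed by Adgrg2, an adhesion G protein-coupled receptor gene (1.14 and 0.79), Ddah1, whose enzyme degrades asymmetric dimethylarginine (0.79 and 0.78), and Tnfsf9 (4.30 and 0.72). Genes that fell with both included H19 (-4.66 and -1.56), Myh1 (-1.52 and -1.47), Agt (-1.43 and -1.38), Aldoc (-1.71 and -1.36), the lipoprotein gene Apoe (-1.38 and -1.33), Sfrp2 (-2.65 and -1.25) and Aspn (-2.74 and -1.22). Ecrg4, below background in all arrays with an shRNA, was at least 2.80-fold lower in both groups. Opposite changes included Cdsn (-1.52 in VEGF-down and 1.73 in VEGF-up cells), Car6 (-4.30 and 1.42), the mitochondrial gene Chchd10 (-1.17 and 0.91), Cth (-3.08 and 0.90) and Angptl6 (-2.69 and 0.79). Ly6e was at least 2.25-fold lower in VEGF-down cells and rose in VEGF-up cells (1.25). In the other direction were Prg4 (1.61 and -1.58), Ces1g (1.62 and -1.40), Mmp3 (1.32 and -1.24), Gdpd2 (0.98 and -1.07), Ifit1 (1.17 and -0.89) and Crip1 (1.02 and -0.88).

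**Figure D4:**
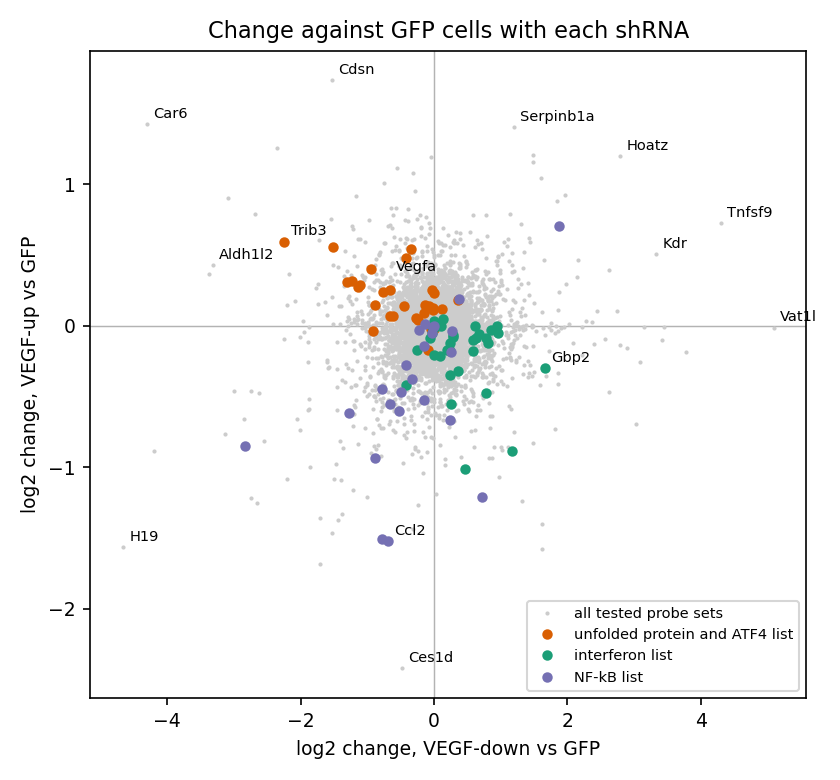
Log2 change of each tested gene against GFP cells in VEGF-down (horizontal) and VEGF-up (vertical) cells, 4 arrays per group, with members of the unfolded protein and ATF4 response, interferon-stimulated and NF-kB lists in colour. The 31 unfolded protein and ATF4 response genes have medians of -0.34 and 0.14 (-0.65 and -0.03 with spike-in scaling), and the 44 interferon-stimulated genes of 0.21 and -0.08 (-0.10 and -0.25).

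Markers of cell types were also read as levels in GFP cells. Of the 26 endothelial markers, 17 were at or below background in all groups, among them Pecam1 at 2.43 and Cdh5, the VE-cadherin gene, at 2.61. Cd34 at 8.44 and Egfl7 at 6.21 were above it. Of the 18 smooth muscle and fibroblast markers 14 were above background, with Acta2 at 13.2, Dcn at 12.9 and Tagln at 12.2. Of the 16 blood cell and macrophage markers 10 were at or below background, and Cd14 was at 9.58.

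**Figure D5:**
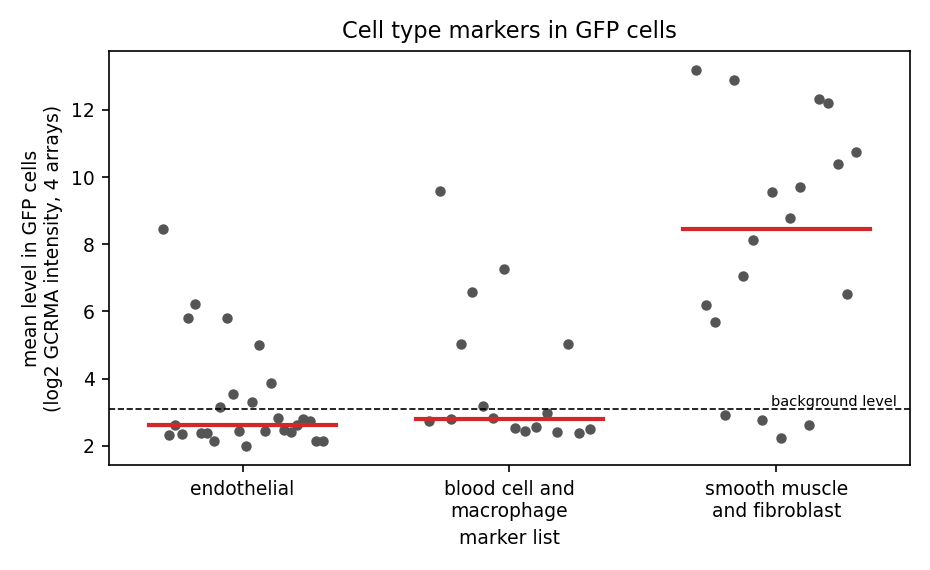
Log2 level in GFP cells (mean of 4 arrays) of each measured marker gene by cell type list, with the background level of 3.09 as a dashed line and the median of each list as a red line. Of the endothelial markers 17 of 26 lie at background in all groups, against 4 of 18 smooth muscle and fibroblast markers.

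The authors' deposited tables list 1204 genes for the VEGF-down shRNA, 617 rises and 587 falls, and 794 for the VEGF-up shRNA, 325 rises and 469 falls. Every listed gene had the same sign in the fit to the arrays, where 1203 and 781 of them passed the test, and 1 and 13 did not. The largest folds in the authors' deposited tables were rises of Vat1l (34.7, from a mean below background), Tnfsf9 (19.8) and Dkk2 (12.9) and falls of H19 (25.5), Car6 (18.9) and Tnnt2 (18.6) for VEGF-down. For VEGF-up the authors' deposited table has Cdsn (3.26), Car6 (2.62) and Serpinb1a (2.57) as the largest rises, and Ces1d (5.37), Ecrg4 (3.20, to a mean below background) and H19 (2.99) as the largest falls. At the smallest fold of each table, 1263 and 865 genes passed the test in the fit, of which 1162 and 748 are in the authors' deposited tables. Both tables share 317 genes, 175 with the same sign and 142 with opposite signs.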

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

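The tests chosen only after the result was seen were those of the GFP arrays, of further amino acid response genes, of dim probe sets, of spike-ins and control probe sets, of spike-in scaling and of outlying arrays.

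The unfolded protein and ATF4 response list moved in opposite directions with the shRNAs, lower in VEGF-down and higher in VEGF-up cells, and differed between them with an adjusted p of 3.71e-14. A deviation of the GFP arrays that both comparisons share cannot be told apart from opposite changes. The list differs between the shRNAs without these arrays (adjusted p = 1.91e-12), a value that does not use them and so does not fix the sign of either change. A bias of the normalization that depends on level is excluded, since a share of only 0.0001 of 10000 random lists of the same levels, the smallest share these can give, lay as far out. The 2 added lists of aminoacyl-tRNA synthetases and amino acid response genes moved the same way, with a largest adjusted p of 0.0352 with an estimated correlation. A shared control of these targets would give this. The lists were chosen after the result was seen and read on the same arrays, so they are no independent test of it. The higher level in VEGF-up cells is relative to other genes, since the median of 0.14 becomes -0.03 with spike-in scaling.

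Endothelial markers were at background in all groups for 17 of 26 genes, although the line is described as endothelial. A general share of dim probe sets does not account for this, since random lists of the same size had a median of 10 at background and only a share of 0.00280 had as many. Probe sets that do not respond cannot be told apart from absent transcripts here: 9 of the markers were above background in at least 1 group, and no RNA known to hold the others was analysed.

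The poly-A spike-ins, signals outside the gene comparisons, were 0.309 higher in VEGF-down than in GFP cells (exact permutation p = 0.0286, adjusted p over all control classes and comparisons 0.06). In VEGF-up cells they were 0.171 higher than in GFP cells, with overlapping arrays (exact permutation p = 0.0857, adjusted p = 0.138). The hybridization spike-ins, added later, differed by 0.0349 between VEGF-down and GFP cells, so no shift of the normalized arrays as a whole accounts for the 0.309. Brightness before normalization cannot be judged, since the array medians of the deposited values were already level. Whether the VEGF-down samples held less mRNA per amount of total RNA or received more spike-in cannot be told from the difference of 0.309.

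Interferon-stimulated genes also moved in opposite directions with the shRNAs and differed between them with an adjusted p of 1.61e-08. The fall in VEGF-up cells was lost with an estimated correlation (adjusted p = 0.124), and with spike-in scaling the medians were -0.10 and -0.25, both negative. The pyruvate carboxylase control probe sets, also outside the gene comparisons, were 0.292 higher in VEGF-down than in GFP cells (exact permutation p = 0.0286, adjusted p = 0.06). Their levels, 3.44 and 3.15, lay close to the background level of 3.09. The Gapdh controls were 0.39 and the 18S rRNA controls 0.14 lower in VEGF-down than in GFP cells, with the same p-values.

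An array far from the other 3 of its group was found in 16 of 84 groups over 28 measures, where chance gives about 1 in 20, or 4.2; the measures share arrays. For single genes and controls these were Vegfa in GFP replicate 2 (7.37), the Gapdh controls in GFP replicate 4 (12.7), the beta-actin controls in VEGF-up replicate 3 (13.2) and the transferrin receptor controls in GFP replicate 2 (2.82). For mean levels of lists in GFP cells they were NF-kB genes in replicate 2 (7.50), the RNA interference machinery in replicate 1 (8.66), smooth muscle and fibroblast markers in replicate 2 (7.95) and blood cell markers in replicate 4 (4.01). In VEGF-down cells they were chromatin silencing enzymes (7.75), extracellular matrix genes (9.87) and ribosomal protein genes (11.2) in replicate 1 and hypoxia genes in replicate 4 (7.26). In VEGF-up cells they were hypoxia genes (7.32) and smooth muscle and fibroblast markers (7.98) in replicate 2, ribosomal protein genes in replicate 3 (11.1) and blood cell markers in replicate 1 (3.82).

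Other divisions of the arrays of each comparison gave no count of changed genes near the real one. The real division stood alone at 1 of 35 each time, the lowest share that 35 divisions can give. The other divisions mix the groups, so the difference between groups adds to their spread and lowers their counts. Chance differences between cultures cannot be excluded in this way, since the replicates may not be separate cultures. The real counts were 5358, 2291 and 5288 and the highest others 0, 1 and 0. For the 856 genes changed the same way by both shRNAs, 1 of 100 divisions, the real one, reached the count and the highest other was 0, with the same limits. For the number of lists past the test chance cannot be excluded: 9 of 35 divisions gave as many as the 4 lists in VEGF-down cells, 2 of 35 as many as the 7 in VEGF-up cells and 9 of 35 as many as the 4 between the shRNAs, with a highest other of 9 each time. Each list past the test but 1 had its largest median in the real division (1 of 35). The exception was blood cell and macrophage markers in VEGF-up cells (5 of 35). Lists that did not pass could rank the same, among them NRF2 and ribosomal protein genes in VEGF-down cells (1 of 35 each). The other divisions mix the groups and so shrink the median of any list that differs. This rank therefore does not set the lists past the test apart. By the p-value of the list, as many as 4 of 35 divisions in VEGF-down cells, 13 in VEGF-up cells and 17 between the shRNAs gave one as small for cell cycle genes. It was 2 of 35 for the unfolded protein and ATF4 response list in VEGF-down cells, and 5 and 4 for cholesterol synthesis genes and blood cell markers in VEGF-up cells. For the other lists past the test it was 1 of 35.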

How the results depend on the processing

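Scaling to spike-ins and keeping only probe sets above background were chosen after the data were seen, and all other alternatives before. For Vegfa every alternative and every left-out array kept the direction and the side of the threshold, except the rise in VEGF-up cells with spike-in scaling (0.17, adjusted p = 0.1002). That value follows from the construction, which shifts all genes of the comparison. A 2-fold minimum left 321 changed genes in VEGF-down cells, 38 in VEGF-up cells, 401 between the shRNAs and 17 changed the same way by both, and 316 and 36 genes of the authors' deposited tables, since most changes are small. A threshold of 0.01 left 1423 in VEGF-up cells. Median centring gave 10708 in VEGF-down cells and 11521 between the shRNAs, of which 5050 and 5103 were at background; the cause was not tested. Spike-in scaling gave 15048 in VEGF-down cells and 2381 changed the same way. Fry does not set a list against other genes, so its counts answer another question than those of camera. In the order VEGF-down, VEGF-up and between the shRNAs, the number of lists past the test was 15, 13 and 14 with fry. With an estimated correlation it was 2 in VEGF-up cells and 2 between the shRNAs, with probe sets above background only 7 in VEGF-down cells and 2 between the shRNAs, with quantile normalization 8 and 2, with spike-in scaling 8 in VEGF-down cells, and without the dimmer probe sets 2 between the shRNAs. Apart from fry, the cause of these differences in the number of lists was not tested. With 1 array left out, the number of lists ran from 4 to 7 in VEGF-down cells (7 without GFP replicate 2), from 5 to 10 in VEGF-up cells and from 2 to 5 between the shRNAs. The counts of changed genes then ran from 4557 to 5277, from 1883 to 2455 and from 4836 to 5054, and the genes changed the same way from 684 to 974. A replicate block gave 4876, 2085 and 5084 changed genes; residuals correlated over 0.1 in 1 of 12 pairs of the same number (-0.13 to 0.20) and 2 of 12 arrays correlated best with their own number. No change of a named gene that passed the test reversed, and Atf4 in VEGF-up cells, not past the test, was at -0.10 with spike-in scaling. Alternatives that average probe sets of a gene could not apply, since each gene has 1. Signal over background limits what can be said of the 37.2% of probe sets with a mean at or below it.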

Other observations

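The tests in this part were chosen after the first results were seen. So were all its lists but those of the interferon-stimulated genes and of the smooth muscle and fibroblast markers. Of 18 aminoacyl-tRNA synthetase genes, 1 rose and 12 fell in VEGF-down cells, with a median of -0.48 (adjusted p = 5.13e-06; 0.0352 with an estimated correlation). In VEGF-up cells 12 rose and 0 fell, with a median of 0.23 (adjusted p = 6.33e-14; 0.00342 with an estimated correlation). Iars was at -1.30 and 0.38, Eprs at -0.79 and 0.39 and Aars at -0.78 and 0.37. Of 17 amino acid response genes outside the fixed list, 2 rose and 14 fell in VEGF-down cells (median -0.53, adjusted p = 7.07e-09; 0.000627 with an estimated correlation), and 7 rose and 2 fell in VEGF-up cells (median 0.11, adjusted p = 2.76e-06; 0.00301 with an estimated correlation). Among them were the translation inhibitor gene Eif4ebp1 (-1.34 and 0.28), Gpt2 (-1.14 and 0.61), Pck2 (-0.98 and 0.20) and Aldh18a1 (-0.78 and 0.40). Vegfa and Gtpbp2 moved in the same directions as these lists. With spike-in scaling the rises of Iars, Eprs, Aars, Eif4ebp1 and Pck2 in VEGF-up cells did not pass the test.

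Besides H19, some other imprinted genes fell in VEGF-down cells. Of 27, 2 rose and 10 fell (adjusted p = 0.00347), a call lost with an estimated correlation (adjusted p = 0.226). Mest was at -1.16, Nnat at -0.78 and Igf2 at -0.68. The median was -0.01 and the mean -0.35, and 11 of the 27 were at background in all groups. In VEGF-up cells 1 rose and 5 fell (adjusted p = 0.0304; 0.312 with an estimated correlation), with Igf2 at -0.69 and Peg3 at 0.60. Of 21 genes of striated muscle filaments, 1 rose and 5 fell in VEGF-down cells (adjusted p = 0.0196; 0.226 with an estimated correlation), and 0 rose and 3 fell in VEGF-up cells (adjusted p = 0.0304; 0.312 with an estimated correlation). The medians were -0.01 in both, the means -0.46 and -0.15, and 12 of the 21 were at background in all groups. Both lists were written after falls such as those of H19 and Tnnt2 had been seen, so their p-values are no independent test.

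A general response to making an shRNA was tested as a source of the interferon-stimulated genes in VEGF-down cells. In VEGF-up cells 0 of the 44 genes rose, 9 fell and 35 did not pass the test. The median of the list there was -0.0754. It stayed negative with each array left out in turn (-0.0763 to -0.0545) and with every alternative (-0.247 to -0.0551). The call of the list as lower was lost with an estimated correlation (adjusted p = 0.124). A response that raises these genes with any shRNA would not leave them without a rise in VEGF-up cells, so these values argue against it for this list. A deviation common to all GFP arrays would shift the signs against GFP cells and is not excluded. A response of the same size to both shRNAs would leave no difference between them, and the list differed (median -0.36, adjusted p = 0.00845 with an estimated correlation).

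Some mesothelial markers were above background in GFP cells, among them Upk3b at 11.7 and Wt1 at 10.1, and 12 further markers not yet looked at were then read. Their median level was 9.11, against 5.05 in random lists of the same size, of which a share of 0.00130 had a median as high. Levels of different probe sets also depend on the probes, so this share cannot tell how strongly the genes are expressed. Gpm6a was at 12.1, Ptgis at 11.5 and Pdpn at 10.1. In VEGF-down cells, where the smooth muscle and fibroblast markers fell (median -0.36), 7 of the 12 rose and 3 fell (adjusted p = 0.0154), and in VEGF-up cells 0 rose and 5 fell (adjusted p = 0.0108). Of the 10 markers looked at first, 6 rose and 2 fell in VEGF-down cells (adjusted p = 0.000583), and in VEGF-up cells 2 rose and 5 fell, not past the test (adjusted p = 0.170). Whether the cells are mesothelial was not tested.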
